A study of Mus musculus with 4 samples.

How the data were processed

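RNA sequencing was done on cultured mesenchymal stem/progenitor cells of mouse bone marrow, with 2 libraries labelled Tet2 knockout and 2 labelled wild type. The authors deposited 1 table with a value in FPKM for each of 41029 genes in each library; every column was mapped to a library, and none was left out. The submitters' processing notes name Bowtie2 2.2.3, TopHat2 2.0.12 and HTSeq 0.6.1 and the genome build mm10, without saying how the gene lengths behind the FPKM were set. FPKM are scaled to the library's total of reads over genes, so a rise in a few abundant genes lowers the rest. The 10 most abundant genes took 6.37%, 10.3%, 7.48% and 7.24% of reads in knockout 1, knockout 2, wild type 1 and wild type 2. Gene names and coordinates came from GENCODE release M21 (GRCm38, the same assembly as mm10), which holds 40535 of the gene identifiers.

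The deposited FPKM proved to be exact quotients of whole numbers, so the total of reads over genes and each gene's reads were worked out from them. For all 25309 genes above 0 a whole read count was found in every library, to within 1e-06 of a read or, for large counts, a bound that grew with the count. The totals ran from 10096878 to 21337246 reads per library, and the reads found this way add up to between 97.68% and 97.84% of them. Where a gene's counts share a common factor this gives the smallest set of counts, so they are lower bounds. They were used for depth, for the shares of abundant and mitochondrial reads, for the comparison of Ftl1 with its copies and for 1 added fit. The main limma and list tests did not use them. Gains and losses set between Ftl1 and its copies thus rest on lower bounds.

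Tests used limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), for genes with a mean of at least 1 FPKM over the 4 libraries, with a mean-variance trend, two-sided p-values and Benjamini-Hochberg adjustment over 12344 genes; genes under 0.05 are called past the threshold. With 2 libraries against 2, an exact permutation test of 1 gene cannot go below p = 0.33, which is why the spread was pooled across genes. Log2 differences are knockout-labelled minus wild type and include the pseudocount of 1, while folds are ratios of mean FPKM. Each of 42 gene lists was fixed from textbook knowledge, and the 34 with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists, then with the correlation estimated from the data and with fry. By camera 11 lists passed, and with an estimated correlation none did. That second setting rests on the 2 residual degrees of freedom of the fit, so hardly any list could pass adjustment over 34. For interferon-stimulated genes the unadjusted p went from 4.04e-13 to 0.0144 (camera), although their estimated correlation was only -0.009. For that list the lost call therefore does not show that correlation between genes made it. Estimates were also low for Hox (0.014), cytokine (0.04), immediate-early (0.056) and ribosomal genes (0.099). They were far above the preset for hypoxia (0.23), niche (0.241), cell cycle inhibitor (0.431), osteogenic (0.519), mitochondrial (0.586) and histone genes (0.676). There correlation between genes may have made the preset call, and this setting cannot decide it. The directional test of fry, which asks whether a list's genes move on balance 1 way and does not compare them with other genes, passed none of the 34 lists, with a smallest adjusted p of 0.052. A second count took genes at least 2-fold apart, on the same log2 scale, in every pair of a knockout-labelled and a wild-type library.

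The lists, alternatives and the rule for naming genes were set before the data were examined, as were the tests other than those under other observations. The rule takes the TET and DNMT list; up to 12 genes per direction past the threshold, named and without overlap between the groups, filled up to 5 by smallest p where fewer pass; up to 4 members of each list past the threshold (6 for the niche, lineage, chemokine and cytokine lists), or 2 by smallest p where none passes; the 5 most abundant genes; and the sex-linked transcripts. Of the genes it yields, the text prints those that describe each group. Genes outside it are said to be chosen after their values were seen, which holds too for Ftl1, Egfl7, Gbp3 and Gbp2b, for the count of 2-fold pairs and for the medians per chromosome. Those medians used genes with a mean of at least 5 FPKM on chromosomes 1 to 19 and X.

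The fit was tested on simulated data with the measured means and spreads. Changes were placed only in genes of higher wild-type level and on the log2(FPKM + 1) scale, so genes near the filter were not tried. With the measured spreads, 10.2% of unchanged genes had an unadjusted p under 0.05, and 82.8% of changes of 4 and 88.2% of changes of 5 on the log2 scale were called. If both groups had the spread of the wild type, 86% of 2-fold changes would be called, with a mean of 15 false calls. In that case 8.29% of unchanged genes had an unadjusted p under 0.05. In these simulations false calls exceeded what the adjusted p states at equal spread too, and more so with the measured spreads. Each simulated spread was taken from the difference between the replicates of a group, which is imprecise and often near 0. The shares and false calls may come from that setting, so they do not measure the error or the power of the real fit. Alternatives covered the pseudocount, the filter, scaling between libraries, the variance model, a block for replicate number, each library left out in turn, the threshold and the list test; a voom fit on the whole reads and a fit with 1 weight per group were added after the data were seen. Computing and figures used Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.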

Results

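RNA was sequenced from mesenchymal stem/progenitor cells of mouse bone marrow, the adherent stromal cells that can form bone, fat and cartilage and that make the signals blood stem cells depend on. The cells were grown in culture and came from C57BL/6 mice. Of the 4 libraries, 2 are labelled Tet2 knockout and 2 wild type. Tet2 is an enzyme that oxidises methylated cytosine in DNA, and the design asks what its loss does to gene expression in these cells. Each library gave a value in FPKM, the reads of a gene scaled to its length and to the library's total of reads over genes. The reads over genes came to 15847340 in the library labelled Tet2 knockout 1, 21337246 in knockout 2, 10096878 in wild type 1 and 17778152 in wild type 2. Between 12039 and 12342 genes reached 1 FPKM in a library. The labels do not say that replicates are separate animals or cultures, so the p-values below measure only the spread between these 4 samples.

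Tet2 itself was not lower in the libraries labelled knockout. It stood at 11.6 and 9.70 FPKM there and at 7.01 and 8.39 FPKM in the wild-type libraries, from 648 and 731 reads against 250 and 527. The difference was 0.42 on the log2 scale (SE 0.18) and did not pass the test (adjusted p = 0.329, limma). It passed, still on the higher side, only without knockout 2 (log2 0.54), where the lone knockout-labelled library is assumed to vary like the wild type. The gene (ENSMUSG00000040943) lies on the minus strand of chromosome 3, from 133463679 to 133545139 in the mouse build GRCm38. A gene total cannot show whether an exon is missing, so the level neither proves nor rules out the genotype. For that reason the libraries are called by their labels throughout, and every direction below is the difference between the libraries so labelled.

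No other gene of DNA methylation and demethylation passed either. Tet3 stood at 8.87 ± 0.213 FPKM in the knockout-labelled libraries and 7.48 ± 0.285 in wild type (mean ± SD, n = 2 each), and the maintenance methyltransferase gene Dnmt1 at 28.5 ± 8.01 and 21.2 ± 0.117. Dnmt3a, a de novo methyltransferase gene, reached 23.3 FPKM in knockout 2 but 8.23 in knockout 1, beside 9.46 and 8.74 in wild type. Gadd45a, a stress-response gene linked to demethylation, had the largest difference of the 12 tested members, at 15.9 ± 0.578 against 39.3 ± 5.46 FPKM (log2 -1.25, adjusted p = 0.156). In this list 1 member was lower when adjusted over the list alone. The list as a whole did not pass (adjusted p = 0.532, camera).

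Of 12344 genes tested, 2 passed the threshold, 1 in each direction. Eng, which encodes endoglin, a co-receptor for transforming growth factor beta and a surface marker of these stromal cells, fell in both knockout-labelled libraries. Its level was 1.53 and 1.59 FPKM there against 110 and 102 FPKM in wild type, a 67.8-fold difference of the means (log2 -5.38, SE 0.13, adjusted p = 0.0237). Eng (ENSMUSG00000026814) lies on chromosome 2 from 32646595 to 32682669, and its value rests on 47 and 66 reads against 2155 and 3505. Ftl1-ps1 (ENSMUSG00000062382, chromosome 13 from 74399694 to 74407346), a copy of the ferritin light chain gene Ftl1 that the annotation lists as protein coding, rose from 1.04 ± 0.255 to 90.7 ± 9.21 FPKM (log2 5.49, SE 0.17, adjusted p = 0.0342), a call that ended with a pseudocount of 0.1 or 0.01 (adjusted p = 0.0586 and 0.0624). A second copy, Ftl2-ps, stood at 14.6 ± 4.14 FPKM against 0.281 ± 0.11 without passing (adjusted p = 0.119). Ftl1 itself was lower in both knockout-labelled libraries, at 823 and 132 FPKM beside 1510 and 1433, and these values cannot separate reads that the gene and its copies share.

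Behind these came genes whose replicates were close and whose differences were large but did not pass. Cxcl12, the chemokine that holds blood stem cells in the marrow, stood at 45.0 ± 2.28 FPKM in the knockout-labelled libraries and 294 ± 4.27 in wild type (log2 -2.68, SE 0.11, adjusted p = 0.0793). Cemip, which breaks down hyaluronan, stood at 60.6 ± 2.08 against 262 ± 2.58 FPKM, and Gsc, a homeobox transcription factor gene, at 0.211 ± 0.194 against 15.0 ± 0.151 (adjusted p = 0.0808 for each). Grem1, an antagonist of bone morphogenetic proteins, stood at 3.22 ± 0.593 against 27.4 ± 0.35 FPKM (adjusted p = 0.0867). In the other direction Tfpi, an inhibitor of coagulation, stood at 36.3 ± 8.63 against 0.252 ± 0.0556 FPKM, and Sfrp2, a secreted modulator of Wnt signals, at 311 ± 11.8 against 71.2 ± 2.70 (adjusted p = 0.0808 for each). Cwc22, a splicing factor gene, stood at 63.8 ± 8.07 against 12.3 ± 0.508 FPKM (adjusted p = 0.0907).

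**Figure D1:**
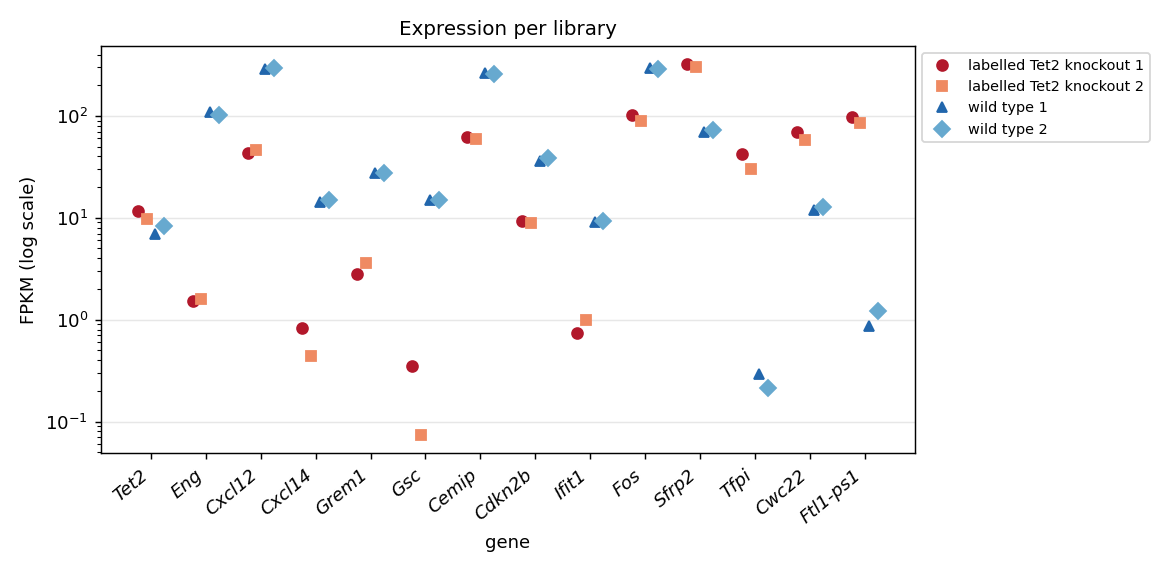
Expression in FPKM on a log axis for 14 genes, with 1 point per library: the 2 libraries labelled Tet2 knockout and the 2 wild-type libraries. Eng stands at 1.53 and 1.59 FPKM in the knockout-labelled libraries and at 110 and 102 in wild type, while Tet2 stands at 11.6 and 9.70 against 7.01 and 8.39.

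The number of calls depended on which libraries were used. Without wild type 1 or without wild type 2 no gene passed in limma, with 274 and 312 genes at an unadjusted p under 0.05, and the adjusted p of Eng was 0.644 and 0.583. A voom fit on the reads behind the FPKM, added after the data were seen, called none, with 2044 at an unadjusted p under 0.05 and an adjusted p of 0.107 for Eng. Without knockout 1, 7415 genes passed and without knockout 2, 5734 did, but both counts let the lone knockout-labelled library borrow the spread of the wild type, which was 4.22 times smaller. On simulated data with the measured spreads of this comparison, 12344 genes and known changes, limma called 39% of the 2-fold and 62.6% of the 4-fold changes, with a mean of 43.7 false calls. The changes were set on the log2 scale used for the tests and only in genes of higher wild-type level. These shares therefore do not cover genes near the filter. Each simulated spread came from the difference between the replicates of a group, which is imprecise and often near 0. The shares and the false calls describe that setting and do not measure how often the real fit missed or erred. At an unadjusted p under 0.05 there were 2114 genes, 1091 higher and 1023 lower, 17.1% of those tested, where 10.2% of unchanged genes had such a p in the simulation. The simulation drew each gene independently, whereas genes of whole chromosomes shifted together in these libraries, as given below. The gap between these shares therefore does not measure how many genes truly differ.

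A count that needs no model asked which genes differed at least 2-fold in every pair of a knockout-labelled and a wild-type library. There were 98 such genes on the higher side and 139 on the lower side, and 20 and 23 of them differed at least 4-fold. Besides the genes above, the lower side held the chemokine gene Cxcl14 (0.634 ± 0.278 against 14.7 ± 0.401 FPKM), the cell cycle inhibitor gene Cdkn2b (9.10 ± 0.398 against 37.1 ± 1.87) and the cartilage matrix gene Comp (0.094 ± 0.051 against 2.82 ± 0.222). The higher side held the collagen genes Col5a3 (6.52 ± 1.79 against 0.447 ± 0.0933 FPKM) and Col15a1 (11.5 ± 2.97 against 1.43 ± 0.512), and Sycp1 (5.33 ± 0.149 against 0.164 ± 0.0902), a meiosis gene that DNA methylation silences in somatic cells. The balance of directions depended on the pseudocount of 1: there were 195 higher and 176 lower genes with a pseudocount of 0.1, and 212 and 183 with 0.01. The 2-fold count was 370 higher and 293 lower without knockout 2, and 635 and 724 without knockout 1.

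Interferon-stimulated genes, the antiviral response genes, formed the list with the smallest p by camera at its preset correlation. Of 30 tested members, 26 lay below both wild-type libraries in both knockout-labelled ones, with a median log2 difference of -0.79. Over all 12344 genes tested, 6686 (54.2%) lay either above both or below both in this way. Counts of this kind, here and for the lists below, start from that high share. Ifit1 stood at 0.862 ± 0.178 against 9.22 ± 0.17 FPKM and Oasl2 at 2.22 ± 0.11 against 9.09 ± 1.04. No member passed over all genes, whereas 16 did when adjusted over the list alone, 15 lower and 1 higher. The list fell relative to other genes by camera with its preset correlation (adjusted p = 1.37e-11). With its estimated correlation of -0.009 it did not pass (adjusted p = 0.489, camera), a setting in which 2 residual degrees of freedom leave little power.

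Immediate-early and heat shock genes, which respond within minutes to growth signals and stress, were lower in both libraries as well. Fos stood at 95.3 ± 9.14 against 290 ± 5.36 FPKM and Dusp1 at 48.6 ± 11.2 against 134 ± 5.31, and 17 of 27 tested members lay below both wild-type libraries. Genes of hypoxia and glycolysis went the same way, with 19 of 30 below both. Egln3, an oxygen sensor gene, stood at 1.89 ± 0.68 against 10.1 ± 0.515 FPKM, and Pfkl, a phosphofructokinase gene of glycolysis, at 86.8 ± 14.3 against 207 ± 12.8. Adjusted over the list alone, 7 immediate-early and heat shock genes were lower, and of the hypoxia genes 5 were lower and 1 higher. Both lists fell by camera (adjusted p = 4.30e-06 and 5.91e-06), and neither held when the correlation was estimated (adjusted p = 0.745 and 0.769 with an estimated correlation).

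Hox genes, which keep the positional identity of stromal cells, lay below both wild-type libraries in 20 of 27 tested members. Hoxc9 stood at 5.42 ± 0.525 against 14.8 ± 1.03 FPKM and Hoxa5 at 5.26 ± 1.5 against 19.1 ± 1.2, and 6 members were lower when adjusted over the list alone. Of the cell cycle inhibitors and targets of the tumour suppressor p53, 14 of 26 lay below both, with Cdkn2b the clearest and 5 lower when adjusted over the list alone. Cdkn1a, the best known p53 target, stood at 211 and 165 FPKM beside 211 and 197; it was looked up after the values were seen. Both lists fell by camera (adjusted p = 1.84e-06 and 3.51e-05) and lost the call otherwise (adjusted p = 0.637 and 0.769 with an estimated correlation). The fall of the cell cycle inhibitors and p53 targets lay mostly in knockout 2, with a list median log2 difference of -1.14 there and -0.27 in knockout 1. For Hox genes the medians were -0.51 in knockout 2 and -0.87 in knockout 1.

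Genes for ribosomal proteins were slightly lower, with 44 of 61 below both wild-type libraries and a median log2 difference of -0.38. Rpl26 stood at 285 ± 14.5 against 471 ± 2.64 FPKM and Rps15 at 543 ± 10.8 against 851 ± 1.59. The list fell by camera (adjusted p = 1.06e-09, and 0.745 with an estimated correlation), and no member passed when adjusted over the list alone. Its adjusted p was 0.0171 with quantile normalization (camera). Over all genes the median was -0.087 in the fifth with the highest expression and -0.103 in that with the shortest span. The list was not tested against genes matched on these. Transcripts encoded in the mitochondrial genome were higher, with 9 of 11 above both wild-type libraries and a median of 0.81. mt-Nd1 stood at 3674 ± 444 against 2008 ± 86.1 FPKM and mt-Nd4 at 1979.6 ± 250.1 against 1094 ± 25.4. That list rose by camera (adjusted p = 0.00044; adjusted p = 0.769 with an estimated correlation), and 6 members were higher when adjusted over the list alone. Mitochondrial reads made up 3.42% and 2.77% of reads in the knockout-labelled libraries and 1.68% and 1.72% in wild type.

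Factors by which stromal cells hold and instruct blood stem cells were lower as a list by camera (adjusted p = 0.0242, and 0.769 with an estimated correlation). Of 29 tested members 12 lay below both wild-type libraries and 2 above both, where 54.2% of all genes lay outside on 1 side or the other. In knockout 1, 5 members stood at least 2-fold above both and 2 below, while in knockout 2 the numbers were 1 and 13. Cxcl12 was the 1 member lower when adjusted over the list alone, and Lif, a cytokine gene, stood at 5.81 ± 3.32 against 14.5 ± 0.515 FPKM. Cytokines and growth factors also fell as a list by camera (adjusted p = 0.0406, and 0.769 with an estimated correlation). This list shares genes with the niche list, among them Kitl, Hgf and Lif, so the 2 results are not separate. Of 39 tested members 18 lay below both and 7 above both, and 2 were lower when adjusted over the list alone. In knockout 1, 6 of them stood at least 2-fold above both wild-type libraries and 1 below, while in knockout 2 the numbers were 5 and 13. Mif, a macrophage cytokine gene, stood at 186 ± 17.7 against 368 ± 27.9 FPKM. Replication-dependent histones, with 9 members tested, were lower (adjusted p = 0.0239; adjusted p = 0.769 with an estimated correlation), as in Hist1h1c at 48.1 ± 1.95 against 66.2 ± 0.319 FPKM, and none passed when adjusted over the list alone. Each of these 3 calls ended without knockout 2 (adjusted p = 0.629, 0.631 and 0.277 in that order), and that of the histones without wild type 1 (adjusted p = 0.0863). The niche list lost its call without the filter on low values (adjusted p = 0.0552) and with a mean FPKM of at least 5 (0.143), and the cytokine list with the latter (0.0991), with trimmed-mean scaling (0.0605) and with quantile normalization (0.0511).

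**Figure D2:**
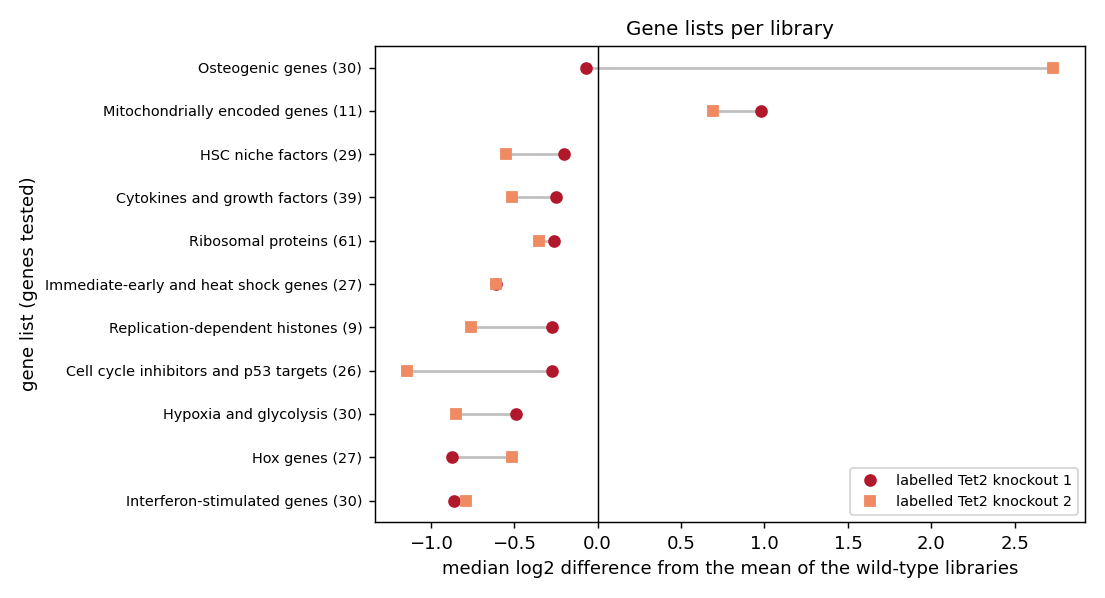
Median log2 difference of each gene list from the mean of the wild-type libraries, with 1 point for each library labelled Tet2 knockout, for the 11 lists that passed with the preset correlation; the number of genes tested stands in brackets. Interferon-stimulated genes lie at -0.86 and -0.79, whereas osteogenic genes lie at -0.07 in knockout 1 and 2.73 in knockout 2.

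Osteogenic genes were higher as a list (adjusted p = 0.0208; adjusted p = 0.769 with an estimated correlation), and this rested on knockout 2. In that library 21 of the 30 tested members stood at least 2-fold above both wild-type libraries, compared with 2 in knockout 1, and without knockout 2 the list turned to the lower side (adjusted p = 0.436). With a mean FPKM of at least 5 it did not pass (adjusted p = 0.091). The examples that follow were chosen after the values were seen. Ibsp, a bone matrix sialoprotein gene, stood at 435 FPKM in knockout 2 and 0.488 in knockout 1, beside 5.17 and 4.95 in wild type. Alpl, the bone alkaline phosphatase gene, stood at 501 FPKM in knockout 2 and 8.21 in knockout 1, beside 6.75 and 6.82. The osteoblast transcription factor gene Sp7 stood at 181 and 1.87 FPKM in that order, beside 5.52 and 5.73. Bglap, which encodes osteocalcin, stood at 65.3 FPKM in knockout 2 and at 0 in knockout 1, beside 0.25 and 0. The members that lay above both wild-type libraries in both were fewer, 10 in all, and included Msx1 (3.44 ± 0.378 against 1.42 ± 0.0304 FPKM) and Smpd3 (4.45 and 49.9 FPKM beside 0.192 and 0.415). No osteogenic gene passed when adjusted over the list alone.

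**Figure D3:**
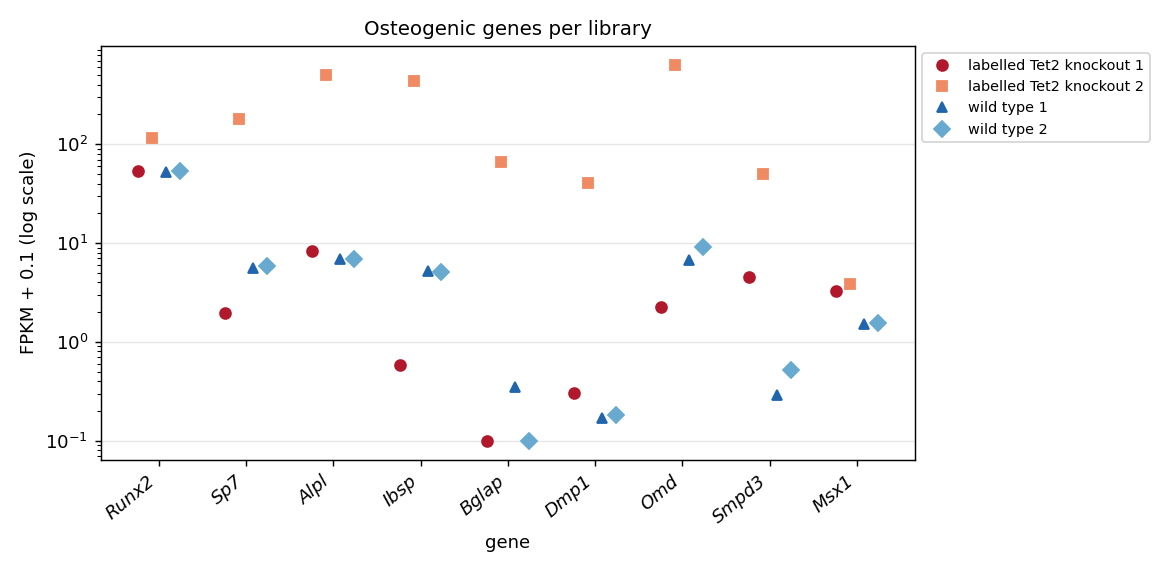
FPKM plus 0.1 on a log axis for 9 osteogenic genes in each of the 4 libraries. Knockout 2 stands apart for Sp7 (181 FPKM), Alpl (501) and Ibsp (435), whereas knockout 1 has 1.87, 8.21 and 0.488 FPKM of these.

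The lists for the other fates and for the matrix did not pass. Among adipogenic genes the desaturase gene Scd1 was the clearest, at 166 ± 19.9 against 84.0 ± 1.60 FPKM, and the 1 member higher when adjusted over the list alone (list adjusted p = 0.236). Among 6 chondrogenic genes Comp was lower when adjusted over the list alone (list adjusted p = 0.847). Of 20 collagen genes, 3 were higher when adjusted over the list alone, with Col5a3 and Col15a1 the clearest (list adjusted p = 0.431). Col1a1 and Col1a2, the main bone collagen genes, stood at 2628 and 3120.0 FPKM in knockout 1 and 13290.0 and 11480.0 in knockout 2, beside 6257 and 6197 in wild type 1 and 5962 and 5965 in wild type 2. Adamts5, a protease gene, was the 1 of 49 matrix genes lower when adjusted over the list alone, at 15.2 ± 1.21 against 41.3 ± 0.76 FPKM (list adjusted p = 0.804). Markers of mesenchymal stromal identity missed the threshold (adjusted p = 0.0554), and Eng was their only member past it. The lists for myofibroblast genes (adjusted p = 0.286) and adhesion receptors (adjusted p = 0.532) held no gene past their own adjustment.

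Signalling and stress lists other than those described above did not pass either, though single genes stood out. Fst, an inhibitor of activin, stood at 10.6 ± 0.43 against 27.6 ± 1.61 FPKM, and with Grem1 belongs to the 3 lower and 1 higher genes of the transforming growth factor and bone morphogenetic protein list when adjusted over the list alone (list adjusted p = 0.532). In the Wnt list Sfrp2 was higher and the receptor gene Fzd2 lower (9.67 ± 0.606 against 21.9 ± 1.03 FPKM) when adjusted over the list alone (list adjusted p = 0.370). In the Notch list the target gene Hes1 was lower, at 68.0 ± 7.98 against 182 ± 17.9 FPKM, and 1 gene higher when adjusted over the list alone (list adjusted p = 0.984). Of 18 chemokines Cxcl12 and Cxcl14 were lower when adjusted over the list alone (list adjusted p = 0.258), and of 25 genes of acute inflammation 3 were (list adjusted p = 0.209), with Saa3 at 0.207 ± 0.0432 against 2.23 ± 0.00967 FPKM. The chaperone gene Hspa5 stood at 1183 ± 6.52 against 660 ± 11 FPKM in a stress-response list with no gene past its own adjustment (list adjusted p = 0.370). Antigen presentation (adjusted p = 0.532), in which Tap2 alone was higher when adjusted over the list alone, cholesterol synthesis (adjusted p = 0.115) and oxidative stress (adjusted p = 0.740) did not pass, nor did the S phase list (adjusted p = 0.532) or that of G2 and M phase (adjusted p = 0.209). The median, the mean and the test differed in sign for the chondrogenic, collagen, matrix, adhesion, chemokine and Notch lists.

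Imprinted and germline genes are known to be controlled by DNA methylation. Of 18 imprinted genes tested, 9 lay below both wild-type libraries and 2 above both, with a median log2 difference of -0.35. The growth regulator gene Grb10 was lower (3.16 ± 0.132 against 9.43 ± 0.424 FPKM) and the antisense RNA Airn higher (5.90 ± 0.753 against 1.85 ± 0.0206) when adjusted over the list alone, and the list did not pass (adjusted p = 0.0554; adjusted p = 0.769 with an estimated correlation). Rian, a noncoding RNA looked up after the values were seen, stood at 7.90 and 0.0333 FPKM beside 22.8 and 21.8. Of 30 germline genes that DNA methylation keeps silent, 3 reached the level for testing, and Sycp1 was higher when adjusted over the list alone.

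The number of markers of other cell types that reached the level for testing differed between lists. No granulocyte or mast cell marker reached it; 1 lymphocyte, 2 epithelial, 2 skeletal muscle, 3 endothelial and 4 erythroid or megakaryocyte markers were tested, too few for a list test. Adjusted over the list alone, Eng was lower and Egfl7 higher among the endothelial markers, and 18 of the 19 others had a mean under 1 FPKM in wild type. The lists for leukocytes (22 tested, adjusted p = 0.747), neural and Schwann cells (8 tested, adjusted p = 0.431) and osteoclasts (5 tested, adjusted p = 0.740) did not pass. Of the leukocyte markers 7 lay above both wild-type libraries and 5 below both, with a list median of -0.04 in knockout 1 and 0.40 in knockout 2. The complement gene C1qb of macrophages, on the lower side, stood at 4.10 ± 0.961 against 10.3 ± 1.03 FPKM, and Map2, a neuronal cytoskeleton gene, at 5.72 ± 1.08 against 17.4 ± 1.63, the 1 neural marker lower when adjusted over the list alone. Xist, which is transcribed from the inactive X chromosome of female cells, had at most 0.0825 FPKM in any library, and each of the 4 libraries expressed genes of the Y chromosome. The 4 tested ones were higher when adjusted over the list alone, Uty at 17.3 ± 0.744 against 9.21 ± 0.189 FPKM, Eif2s3y at 76.6 ± 5.0 against 45.0 ± 2.53, Kdm5d at 15.0 ± 1.45 against 8.81 ± 0.362 and Ddx3y at 52.5 ± 17.5 against 24.2 ± 0.818.

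The wild-type libraries were alike and the knockout-labelled ones were not. Across genes Pearson's r was 0.995 between the wild-type libraries, with 51 genes at least 2-fold apart, and 0.909 between the knockout-labelled ones, with 1543 (genes are not independent replicates). Knockout 1 lay nearer to wild type (r = 0.953 and 0.955) than to knockout 2. Whole chromosomes differed too. Genes on chromosome 7 stood lower in knockout 2 than in wild type by a median log2 of -0.58 relative to the other chromosomes, with 85.5% of 628 genes below, and genes on chromosome 12 stood lower in knockout 1 by -0.49, with 92.3% of 313 below. Chromosome 12 stood at -0.15 in knockout 2. Chromosomes 10 and 11 also stood lower in both, at -0.17 and -0.21 in knockout 1 and -0.25 and -0.18 in knockout 2. So did chromosomes 13 and 18, at -0.1 and -0.23 in knockout 1 and -0.02 and -0.07 in knockout 2. Ftl1 lies on chromosome 7.

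**Figure D4:**
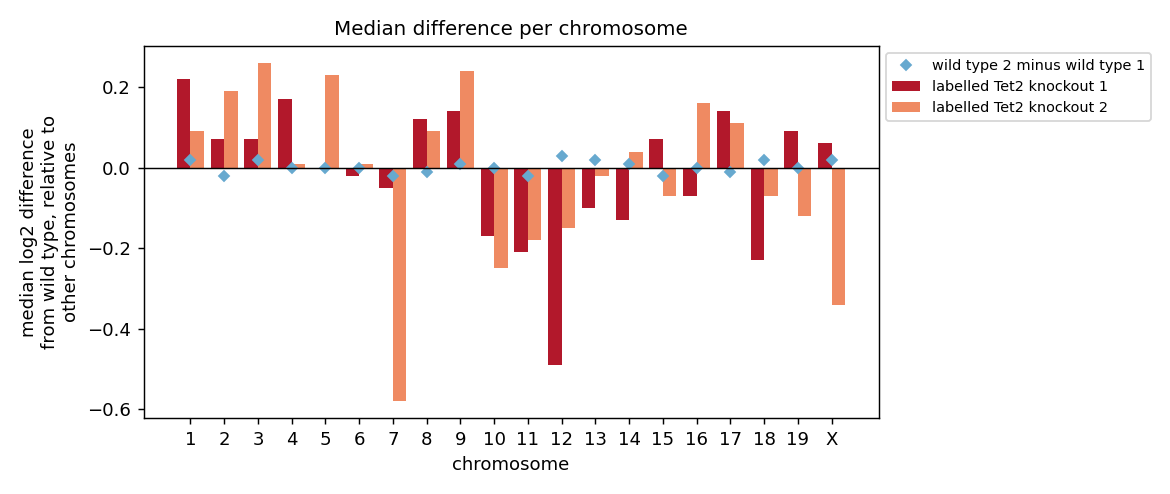
Median log2 difference from wild type per chromosome, relative to the other chromosomes, as bars for the libraries labelled Tet2 knockout 1 and 2, with diamonds for wild type 2 minus wild type 1. Chromosome 7 stands at -0.58 in knockout 2 and chromosome 12 at -0.49 in knockout 1.

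The genes around Tet2 did not differ from other genes as a set. Of 67 tested genes that start within 10 Mb of it on chromosome 3, none passed in limma and 8 had an unadjusted p under 0.05, and the median log2 difference was 0.13 (camera of limma, adjusted p = 0.281, in a family of this 1 test). The directional test of fry, which does not compare them with other genes, passed (adjusted p = 0.0416 in a family of 1). The interferon-induced GTPase genes Gbp3, lower, and Gbp2b, higher, were the 2 that differed at least 2-fold in every pair. Over all genes the median difference was 0.0304, and it ran from -0.103 in the fifth of genes with the shortest span to 0.111 in that with the longest, and from 0.141 in the fifth with the lowest expression to -0.087 in that with the highest.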

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

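The voom fit, the weights per group, and the 2-fold count with all its alternatives were chosen after the data were seen. The count of 2 called genes was kept without the filter, with a mean FPKM of at least 5, with either scaling, with no trend, with robust variances and with a 2-fold minimum. It was 1 with a pseudocount of 0.1 or 0.01, where Eng passed; 0 with voom on whole reads; 16 with weights per group of libraries; and 15 at an adjusted p under 0.1. Leaving out 1 library gave 0 to 7415 calls, and the largest counts assume that a lone knockout-labelled library varies like the wild type. The cause of the other changes was not tested. The adjusted p of Eng ran from 9.2e-08 to 0.644 over the alternatives, and its log2 difference from -6.07 to -5.32. The 237 genes at least 2-fold apart in every pair became 371 and 395 with pseudocounts of 0.1 and 0.01, which widen folds near 0, and 394 with voom (210 higher, 184 lower); leaving out 1 library gave 262 to 1359.

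Of the list tests, 11 passed; 7 did with a mean FPKM of at least 5 (fewer genes), 20 without knockout replicate 1, and 0 with an estimated correlation or with fry. Without 1 library the number ran from 11 to 20. The osteogenic list reversed without knockout replicate 2 (adjusted p = 0.436; 5.43e-11 without knockout replicate 1). The lists for interferon-stimulated, hypoxia, immediate-early, Hox, mitochondrial and ribosomal genes and for cell cycle inhibitors each passed under 15 of 17 alternatives. Genes near Tet2 reached an adjusted p = 0.0416 (a family of 1 test) with fry of limma, which tests the list itself and not against other genes. Tet2 stayed on the higher side under every alternative, at 0.30 to 0.54 without 1 library, and passed at 0.54 without knockout replicate 2. Of single genes, Dnmt3a reversed without knockout replicate 2, with a range of -0.13 to 1.27 (log2) over the libraries left out; Col1a1 without knockout replicate 1 (range -1.22 to 1.12); and Col1a2 without knockout replicate 1 (range -0.96 to 0.92) and without wild type replicate 1, where it was 0.

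Nothing in the labels says that equal replicate numbers belong together. The differences between replicates 1 and 2 in the 2 groups correlated at 0.006 across genes, so no pairing shows, and with replicate number as a block 0 genes passed, with Eng at an adjusted p of 0.13.

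Depth limits genes with few reads, so their folds are imprecise: among others Gsc, Cxcl14, Comp and Saa3 in the knockout-labelled libraries, and Ftl2-ps, Sycp1, Tfpi and Ftl1-ps1 (8 and 20 reads) in wild type. The median SD was 0.244 on the log2 scale in the knockout-labelled libraries and 0.058 in wild type, which limits other genes too.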

Other observations

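The test of endothelial markers, Fisher's tests of pseudogenes and their matching on level, the 2 counts over splits of the libraries, the matching of random genes on local gene density and the segment medians of chromosomes other than 7 were chosen only after the results they bear on had been seen. The other tests below were set before their own results were known, but after the pattern that each addresses had been seen. The library values in the next 2 paragraphs were also picked after they were seen, and no difference between single libraries was tested.

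The library labelled Tet2 knockout 1 had higher levels than knockout 2 of several genes for secreted and surface proteins. Others of this kind, such as Col1a1, went the other way, and no list of secreted or surface proteins was tested. Kitl, which encodes stem cell factor, stood at 52.0 FPKM in knockout 1 and 14.6 in knockout 2, beside 18.6 and 21.4 in wild type. Angpt1, the angiopoietin gene, stood at 15.1 and 1.0 FPKM beside 3.47 and 3.77, and Hgf, the hepatocyte growth factor gene, at 25.7 and 0.175 beside 2.04 and 1.77. The surface marker gene Thy1 stood at 131 and 8.27 FPKM beside 14.9 and 16.0. Lpl, the lipoprotein lipase gene of fat cells, was above wild type in both, at 190.2 and 17.4 FPKM beside 3.33 and 3.56. In all, 370 genes stood at least 2-fold above both wild-type libraries in knockout 1 and 293 below.

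In knockout 2 the numbers were 635 above and 724 below. Besides the osteoblast genes, its cells had 181 FPKM of the antigen presentation gene H2-K1, beside 26.4 in knockout 1 and 52.8 and 48.4 in wild type. Nes, which encodes the filament protein nestin found in niche stromal cells, stood at 0.903 FPKM in knockout 2 and 38.1 in knockout 1, beside 78.7 and 79.4. Of the 26 cell cycle inhibitors and p53 targets, 14 stood at least 2-fold below both wild-type libraries in knockout 2 and 5 in knockout 1. Ccng1, a p53 target, stood at 103 FPKM in knockout 2 and 555 in knockout 1, beside 483 and 508.

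Eng was the 1 gene that fell past the threshold in the knockout-labelled libraries, while Tet2 itself was not lower. Endothelial cells in the wild-type cultures, which would bring their other transcripts, are argued against by a median of 0.0534 FPKM over 19 other endothelial markers in wild type, where the highest, Flt1, stood at 1.64. A lost chromosome segment is argued against by the 28 tested genes within 500 kb of Eng, whose median log2 difference was 0.08, with a range of -0.92 to 0.81. A change in Eng alone, an effect of the genotype on Eng, or a difference in origin between the cultures may each remain, and these 4 libraries hold no test of them.

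Chromosome 7 in knockout 2 may be present in fewer copies in the culture, in all or part of its cells. It had the lowest median of that library, which by itself makes low segments likelier. This hypothesis needs the whole chromosome to be low, and each of its 5 consecutive segments was, with medians of -0.71, -0.67, -0.55, -0.53 and -0.45 on the log2 scale relative to other chromosomes, where chromosome X ran from -0.42 to -0.19 and chromosome 10 from -0.46 to -0.17; the medians of the 19 others ran from -0.34 to 0.26. A bias by GC content or transcript length is argued against, since the median was -0.54 (95% bootstrap interval -0.58 to -0.49) once that trend was removed. The bootstrap resampled the chromosome's genes in knockout 2 alone as if independent, so its interval does not measure spread between cultures. Chromosome 12 in knockout 1 went the same way, at -0.34 to -0.55 per segment and -0.51 without the trend, where the 19 others ran from -0.23 to 0.22, while chromosome X in knockout 2 stood at -0.34 and -0.38 without the trend. DNA was not analysed here, so a copy change cannot be told from a regulatory change along the whole chromosome, and an effect of the genotype on it was not tested. The lowest chromosome differs between the 2 libraries, while chromosomes 10, 11 and 12 stood at -0.15 or lower in both. Chromosome 18 was lower in both too, at -0.23 in knockout 1 and -0.07 in knockout 2.

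Pseudogenes were more frequent among genes at least 2-fold apart in every pair, but not clearly so at matched expression level: 7 of the 98 on the higher side (7.14%, against 2.05% of other tested genes; odds ratio 3.68, Fisher's exact p = 0.00442, two-sided) and 7 of 139 on the lower side (5.04%, odds ratio 2.53, exact p = 0.0267), beside medians of 3 (95% of draws 1 to 8, one-sided permutation p = 0.0654) and 4 (1 to 8, one-sided permutation p = 0.117) in random genes of matched level. Reads moved from Ftl1 to its 2 copies cannot be told apart from expression of the copies. The copies gained 18.7% of the reads, scaled to the library total, that Ftl1 lost in knockout 1 and 7.64% in knockout 2, under the bound of 10% set beforehand, but that bound was wrong: moved reads need Ftl1 to lose at least what the copies gain, and it lost 525.5 and 1085 RPM (reads scaled to the library total) against gains of 98.21 and 82.96. DNA of another strain in part of the genome would crowd such genes together. The rule set beforehand counted a number of close pairs under the random median against this. There were 22 neighbouring pairs within 1 Mb, under the median of 37 in random genes of matched level, but those draws ignored gene density. With it matched the median was 27 (95% of draws 19 to 36, permutation p = 0.9). The rule was set aside after the result, since 22 lies within the range of these draws, which cannot decide. A strain difference spread over the whole genome stays open and untested.

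The 4 libraries can be split into 2 and 2 in only 3 ways, too few for a share under 0.05. The real split called 2 genes and the highest of the others 0, and it gave 237 genes at least 2-fold apart in every pair where the highest other gave 2. In each case 1 split of 3, the real one, gave as many. Each other split sets the 2 wild-type libraries on opposite sides, and these were at least 2-fold apart in only 51 genes. Their likeness thus fixed the low 2-fold counts of the other splits in advance, and the contrast says nothing about the genotype.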
